A study of Homo sapiens with 12 samples.

How the data were processed

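RNA of PC9 and HCC827 cells kept for 8 days in DMSO or in 2 micromolar erlotinib, in medium with 10% fetal bovine serum that was renewed once after day 4, was hybridised to 12 Affymetrix HG-U133 Plus arrays, 3 per group. Per the labels, RNA was purified with the RNeasy Plus kit and amplified and biotin-labelled with NuGEN Ovation reagents. The deposited table holds 1 linear signal intensity per probe set and array, which the authors made with MAS5 (version not given); the values showed that each array had been scaled to the same 2% trimmed mean of 150, and the table has no detection calls. As no call of presence was given, the depth of a value was its signal over the background of the table. All 12 arrays were used and no sample was left out.

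The table has 54675 probe sets, of which 62 are controls, 41091 are paired with 1 gene symbol, 1801 with several and 11721 with none. Of those with 1 symbol, 41037 matched the gene name table by gene ID, and 0 symbols were updated that way. For each of 19775 genes the probe set with the highest mean log2 signal over all arrays was taken. Genes were kept if the mean of at least 1 group reached the median of the table (signal 13), which left 13165. Signals were analysed as log2 of the signal plus 8. The test was run in limma 3.58.1 under R 4.3.3, with 1 mean per group and moderated variances with an intensity trend over all 12 arrays. The contrasts were erlotinib minus DMSO in PC9 and in HCC827, and the PC9 change minus the HCC827 change. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls of at least 2-fold were counted too. Calls shared by the lines were compared with independent lists by odds ratios from Fisher's exact test across genes.

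Before the data were examined, the tests, most alternative settings, the rule for named genes and 21 lists with 430 genes were fixed. Of these genes 355 were measured, 40 were under the filter, 13 were found only on probe sets with several symbols and 22 were not analysed here. The lists were ERK pathway output, EGFR family ligands, receptor tyrosine kinases and adaptors, mitosis, DNA replication, CDK inhibitors and FOXO targets, BCL2 family, epithelial, mesenchymal, lung epithelial lineage, type I interferon response, antigen presentation, NF-kB targets, cholesterol synthesis, glycolysis, lysosome and autophagy, YAP and TAZ targets, ribosome biogenesis, stress response, stem-like and drug-tolerance markers, and markers of leukocytes, endothelium and fibroblasts as cells that a culture should lack. They were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. Named genes were the 6 largest rises and 6 largest falls of each line among called genes with arrays that did not overlap, the 4 largest differences each way, up to 4 called members of each list with the largest changes, of which some are given, and EGFR, ERBB3, MET, AXL, BCL2L11, DUSP6, CCND1, MKI67, CDKN1B, VIM, CDH1 and ETV5.

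The alternatives fixed beforehand were 1 or 32 in place of 8, quantile normalization, centring of each array on its median, no filter or one at the 70th percentile (the stricter filter), the mean of all probe sets of a gene, probe sets tested singly, variances without the trend, the 6 arrays of a line alone, replicate number as a block, a test against 1.5-fold, an estimated correlation and leaving out each array in turn. After seeing the data, the log2 actin 3'/5' ratio as a covariate and a fit without HCC827 erlotinib replicates 2 and 3 were added; in the latter the lone erlotinib array was assumed to vary like the other groups. Tested on simulated data made for the PC9 contrast (13165 genes, 200 changed), the procedure recovered 83% of changes of log2 0.5 and 100% of changes of log2 1, with 8 false calls, 0 calls in unchanged HCC827 and 0 other lists called. The simulated noise was independent between genes, and far fewer genes changed than in the data. It therefore could not show false list calls that come from correlation between genes. Of the 118 named genes, 63 had other probe sets, and 3 of these had 1 called in the opposite direction.

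Some groupings in the closing part were chosen after seeing the data: 12 gene families defined by symbol, which replaced hand-picked genes, and the counts of genes on which 1 array stood apart. The test of 3' bias was first drafted on single arrays and was changed to the covariate fit before its value was known. Its bound for the HCC827 interferon genes was made stricter afterwards, so that the fit without erlotinib replicates 2 and 3 also had to meet it.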

Results

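Messenger RNA was measured on 12 one-colour microarrays in PC9 and HCC827, established human lung adenocarcinoma lines that carry activating mutations of the EGFR gene. Each line was kept for 8 days in DMSO, the solvent control, or in 2 micromolar erlotinib, an inhibitor of the EGFR kinase, and each of the 4 groups held 3 arrays. The arrays had median signals from 11.1 to 14.5, and the number of arrays limited the precision of every value. Arrays of a group correlated across genes with r from 0.9929 to 0.9973. Plated cell number and vessel also differed between the treatments, with fewer cells in 10 cm dishes for DMSO and more in 150 cm flasks for erlotinib. Neither could be told apart from the drug. The series description instead gives 150 cm flasks for all cells, so the vessels are uncertain. Nothing in the labels says whether the arrays of a group came from separate cultures, so the p-values measured only the spread between these samples. Log2 changes were computed after 8 was added to each signal and are given with their standard error. That error pooled the spread of all 4 groups and is the same for both lines. A gene with a wide spread in 1 group, such as VIM in PC9 DMSO, thus has a wide error in both. Signals are given as mean ± SD, n = 3 per group.

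The largest single-gene changes in PC9 after 8 days of erlotinib are given first, and most of the rises started from signals near background, so their order depended on the constant added. With 1 in place of 8, the rises of IL32 and CRISP3 (7.37 for the latter) were larger than that of OLR1. OLR1, a receptor for oxidised lipoprotein, rose from a signal of 10.97 ± 3.81 in DMSO to 1350.0 ± 60.5 in erlotinib, a log2 change of 6.18 ± 0.14. The cytokine IL32 rose by 5.93 ± 0.12 to 571 ± 69.9, and the platelet chemokine PPBP by 5.54 ± 0.13 to 817 ± 78.8. MYL9, a myosin light chain, rose by 5.32 ± 0.19, TMEM52B by 5.19 ± 0.15 and the interferon-inducible GTPase GBP1 by 5.06 ± 0.09. DUSP6, a phosphatase that switches off ERK, fell by 4.15 ± 0.12 on the log2 scale, from a signal of 1358 ± 272 to 68.1 ± 7.23 (adjusted p = 9.58e-14). The interleukin receptor IL1RL1 fell by 4.35 ± 0.16, SPRY4 of the Sprouty feedback inhibitors fell by 4.32 ± 0.10, the transmembrane collagen COL13A1 fell by 3.78 ± 0.14, the calcium-binding S100A9 fell by 3.77 ± 0.11 and the peroxisomal oxidase ACOX2 fell by 3.70 ± 0.17. Each of these 12 genes had adjusted p of 1.14e-11 or lower, and its 3 erlotinib arrays lay beyond all 3 DMSO arrays.

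Of 13165 genes tested in PC9, 8521 changed (64.7%), 4790 higher and 3731 lower, and 1267 of the higher and 449 of the lower changed at least 2-fold. Arrays of the treatments did not overlap for 8549 genes (64.9%), against 10% by chance. With median centring 950 were higher and 683 lower by at least 2-fold, and with quantile normalization 1007 and 572. Higher genes made up 56.2% of the changed genes as deposited and 39.9% (3556 higher, 5367 lower) when each array was centred on its median, which shifted the median change of all genes by -0.165. Tested against a 1.5-fold change, 2202 genes passed.

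The ERK pathway output genes fell as a group in PC9 (median log2 change -1.10, adjusted p = 1.79e-06; adjusted p = 0.0403 with an estimated correlation): 15 of 20 measured members fell, 3 rose and 2 did not pass. Besides SPRY4 and DUSP6, the ETS factors ETV4 and ETV5 fell by 2.72 ± 0.15 and fell by 2.10 ± 0.10, and SPRY1 fell by 2.64 ± 0.09. CCND1, the cyclin of G1 entry, fell by 0.34 ± 0.06 in PC9. The 3 members that rose, named after their values were seen, were the early growth response factor EGR1 (1.17), the ephrin receptor EPHA4 (1.37) and IER3 (0.23).

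Cell cycle genes were lower in erlotinib-treated PC9. All 24 mitosis genes fell (median -0.72, adjusted p = 4.67e-11; adjusted p = 0.0852 with an estimated correlation). The centromere histone CENPA fell by 1.21 ± 0.15, the mitotic kinase AURKB fell by 1.11 ± 0.17 and PLK1 fell by 1.09 ± 0.09. MKI67, the proliferation marker, fell by 0.85 ± 0.09. Among 25 DNA replication genes 24 fell and 1 did not pass (median -0.77, adjusted p = 2.46e-11; adjusted p = 0.0403 with an estimated correlation). GINS2 of the replicative helicase fell by 1.36 ± 0.07, POLE2 of DNA polymerase epsilon fell by 1.28 ± 0.08 and the origin-licensing factor CDC6 fell by 1.20 ± 0.08. Ribosome biogenesis genes fell in 13 of 15 cases, with 2 not passing (median -0.65, adjusted p = 1.79e-06; adjusted p = 0.0863 with an estimated correlation). In that list POLR1B, a subunit of RNA polymerase I, fell by 0.93 ± 0.05, RRS1 fell by 0.92 ± 0.08 and RRP9 fell by 0.91 ± 0.12. Glycolysis genes fell in 13 of 19 cases, rose in 1 and did not pass in 5 (median -0.34, adjusted p = 7.87e-04; adjusted p = 0.231 with an estimated correlation). PDK1, a kinase that inhibits pyruvate dehydrogenase, fell from a signal of 1071 ± 105 to 419 ± 51.6 and hexokinase HK2 from 1421 ± 85.0 to 618 ± 48.2.

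NF-kB target genes rose in PC9 in 13 of 18 cases, none fell and 5 did not pass (median 1.28, adjusted p = 3.66e-04; adjusted p = 0.216 with an estimated correlation), and 1 fell with median centring. The cytokine IL6 went from a signal of 16.7 ± 2.71 to 385 ± 71.6. The adhesion molecule ICAM1 rose by 3.75 ± 0.09 and the neutrophil chemokine CXCL1 by 3.63 ± 0.17. Type I interferon response genes rose in 14 of 23 cases, none fell and 9 did not pass (median 0.76, adjusted p = 8.38e-04; adjusted p = 0.2 with an estimated correlation), and 1 fell under quantile normalization and 2 under median centring. IFIT2, an interferon-induced protein with tetratricopeptide repeats, rose by 1.83 ± 0.09, IFI44 by 1.57 ± 0.12 and the antiviral GTPase MX2 by 1.51 ± 0.12. The median signal of the 23 members was 11.9 in DMSO and 27.6 in erlotinib in PC9, and 287 and 226 in HCC827. Antigen presentation genes rose in 11 of 16 cases, 1 fell and 4 did not pass (median 0.95, adjusted p = 3.02e-04; adjusted p = 0.0403 with an estimated correlation). The immunoproteasome subunit PSMB9 rose by 3.28 ± 0.08, HLA-DMA by 2.21 ± 0.11, HLA-E by 1.31 ± 0.06 and HLA-F by 1.25 ± 0.12.

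In PC9 the lists of CDK inhibitors and FOXO targets, stress response, lysosome, and YAP and TAZ targets rose at the preset correlation only. CDK inhibitors and FOXO target genes rose in 12 of 17 cases, 1 fell and 4 did not pass (median 0.54, adjusted p = 0.00802; adjusted p = 0.231 with an estimated correlation). PIK3IP1, an inhibitor of phosphatidylinositol kinase signalling, rose by 2.71 ± 0.17 and the CDK inhibitor CDKN2B by 2.36 ± 0.08, whereas KLF4, named after its value was seen, fell by 1.52. CDKN1B rose by 0.23 ± 0.07, but its change was 0.13 (adjusted p = 0.0779) without PC9 erlotinib replicate 1 and 0.063 (adjusted p = 0.439) with median centring. Stress response genes rose in 11 of 16 cases, 3 fell and 2 did not pass (median 0.84, adjusted p = 0.00587; adjusted p = 0.192 with an estimated correlation). The transcription factor ATF3 rose by 3.85 ± 0.15 and asparagine synthetase ASNS by 1.86 ± 0.08. Lysosome and autophagy genes rose in 9 of 16 cases, 2 fell and 5 did not pass (median 0.47, adjusted p = 0.0241; adjusted p = 0.231 with an estimated correlation), and the median was 0.19 with quantile normalization and 0.31 with median centring. GABARAPL1, of the autophagosome, rose to a signal of 969 ± 226 (log2 3.57), WIPI1 rose by 2.30 ± 0.11 and the autophagy kinase ULK1 by 1.82 ± 0.15. YAP and TAZ target genes rose in 15 of 20 cases, 2 fell and 3 did not pass (median 0.67, adjusted p = 7.87e-04; adjusted p = 0.204 with an estimated correlation). CCN2 rose by 3.38 ± 0.24, ANKRD1 by 2.99 ± 0.25 and CCDC80 by 2.89 ± 0.07.

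The remaining 9 lists did not pass in PC9. Mesenchymal genes rose in 11 of 20 cases and fell in 3 (median 0.53, adjusted p = 0.0781), with TAGLN up by 2.93 ± 0.12, POSTN by 2.79 ± 0.18 and COL5A1 by 2.70 ± 0.11. Without PC9 DMSO replicate 2 the adjusted p of the mesenchymal genes was 0.00787, and it was 0.0309 with median centring and 0.045 with no filter. On that array SPARC read 69.6 against 1.10 and 1.30 on the other DMSO arrays and VIM read 229 against 74.0 and 74.5. VIM, an intermediate filament, rose by 0.68 ± 0.27 (adjusted p = 0.0343); its change was 1.19 without PC9 DMSO replicate 2, 0.43 (adjusted p = 0.171) without replicate 1 and 0.43 (adjusted p = 0.184) without replicate 3. VIM also missed the threshold without PC9 erlotinib replicate 1 (adjusted p = 0.0579), replicate 2 (adjusted p = 0.104) or replicate 3 (adjusted p = 0.0531). BCL2 family genes rose in 8 of 17 cases and fell in 4 (median 0.16, adjusted p = 0.412), and with median centring 5 rose and 6 fell (median -0.005). In that family BMF and BCL2L11, which promote apoptosis, rose by 3.39 ± 0.10 and 1.00 ± 0.09. HRK rose by 1.56 ± 0.14, and BCL2, which opposes apoptosis, fell by 1.02 ± 0.12. Receptor tyrosine kinases and adaptors rose in 6 of 16 cases and fell in 6 (adjusted p = 0.765), and their median of -0.077 and test (down) differed in sign from their mean of 0.11. With quantile normalization 5 of them rose and 9 fell (median -0.28), and with median centring 6 rose and 9 fell (median -0.24). FGFR3 rose by 1.98 ± 0.10, INSR by 1.05 ± 0.06 and ERBB3 by 0.81 ± 0.07, while IRS1 fell by 1.84 ± 0.09, EGFR fell by 0.48 ± 0.05 and MET fell by 0.47 ± 0.04. AXL had a change of 0.005 ± 0.068 (adjusted p = 0.953), which was -0.16 (adjusted p = 0.0461) with median centring.

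Epithelial genes in PC9 rose in 7 of 20 cases and fell in 4 (median 0.058, adjusted p = 0.476), and with median centring 6 rose and 7 fell (median -0.11). MUC1, a membrane mucin, rose by 2.81 ± 0.12, CLDN1 by 1.94 ± 0.08 and ELF3 by 1.84 ± 0.08, and EHF fell by 0.83 ± 0.07. The cadherin CDH1 had a change of 0.085 ± 0.061 (adjusted p = 0.237), which was 0.17 (adjusted p = 0.00283) with quantile normalization, 0.16 (adjusted p = 0.0252) without PC9 erlotinib replicate 1 and -0.079 with median centring. EGFR family ligands rose in 1 of 7 cases and fell in 3 (median -0.11, adjusted p = 0.327), among them HBEGF, which fell by 1.62 ± 0.09, and EREG, which fell by 1.00 ± 0.12. Lung epithelial lineage genes rose in 2 of 12 cases and fell in 3 (median -0.015, adjusted p = 0.626), including basal keratin KRT5, which fell by 1.49 ± 0.14. Cholesterol synthesis genes rose in 5 of 18 cases and fell in 4 (median -0.094, adjusted p = 0.476); with median centring 2 rose and 11 fell (median -0.26). TM7SF2 rose by 1.16 ± 0.13 and MVK fell by 0.71 ± 0.13. Stem-like and drug-tolerance marker genes rose in 8 of 13 cases and fell in 3 (median 0.31, adjusted p = 0.443), with SOX4 up by 1.47 ± 0.09, the histone demethylase KDM5B by 1.03 ± 0.07, and CD44, which fell by 0.88 ± 0.06. Of the leukocyte, endothelial and fibroblast markers 4 were bright enough to test (adjusted p = 0.476): the fibroblast proteoglycan LUM rose by 3.57 ± 0.14, the endothelial cadherin CDH5 rose by 0.72 ± 0.12, PECAM1 fell by 0.71 ± 0.09 and 1 did not pass. Adjusted over the list alone, 25 DNA replication genes fell, 14 ribosome biogenesis genes fell, 13 CDK inhibitors and FOXO target genes and 10 lysosome genes rose and 2 lung lineage genes fell, and the counts of the other 16 lists were as given.

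**Figure D1:**
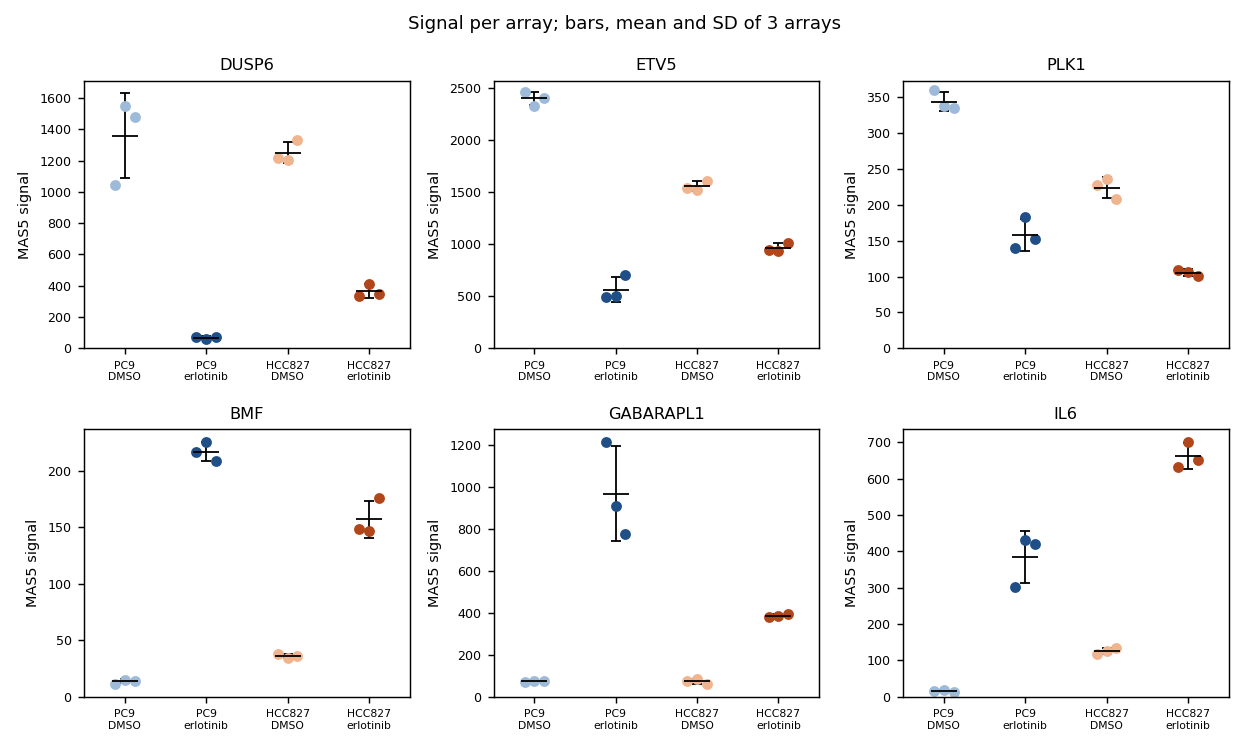
MAS5 signal (arbitrary units, linear axis from 0) of DUSP6, ETV5, PLK1, BMF, GABARAPL1 and IL6 on each of the 12 arrays, by line and treatment; points are arrays, bars are mean and SD of 3 arrays. DUSP6, ETV5 and PLK1 were lower, and BMF, GABARAPL1 and IL6 higher, on all 3 erlotinib arrays than on all 3 DMSO arrays of both lines.

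The 6 largest rises and 6 largest falls in HCC827 included none of those of PC9. The chemokine receptor ACKR3 rose from a signal of 2.23 ± 1.30 to 349 ± 26.9, a log2 change of 5.13 ± 0.10, and the monocyte chemokine CCL2 rose by 4.67 ± 0.21 to 572 ± 33.0. FILIP1L rose by 4.16 ± 0.08, the endothelin EDN2 by 4.05 ± 0.12, the natriuretic peptide precursor NPPB by 4.00 ± 0.20 and the microtubule-associated MAP2 by 3.98 ± 0.11. As in PC9, some of these rises started near background, such as ACKR3, NPPB (3.83 ± 2.48) and CCL2 (14.9 ± 2.40). Their size and order thus depended on the constant added. SPRR1B, a precursor of the cornified envelope, fell by 4.55 ± 0.10, from a signal of 466 ± 37.0 to 12.1 ± 1.03 (adjusted p = 1.01e-14). S100P fell by 4.19 ± 0.08, the immunoglobulin transporter PIGR fell by 3.52 ± 0.10, SPRR1A fell by 3.34 ± 0.12, ACMSD fell by 2.86 ± 0.14 and the keratin KRT16 fell by 2.80 ± 0.16. The 12 genes had adjusted p of 4.7e-10 or lower, with no overlap between arrays of the treatments.

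Of 13165 genes tested in HCC827, 6818 changed (51.8%), 4247 higher and 2571 lower, with 760 higher and 193 lower by at least 2-fold; arrays did not overlap for 8189 genes (62.2%), against 10% by chance. With median centring 581 were higher and 266 lower by at least 2-fold. Higher genes made up 62.3% as deposited and 43.5% (3091 higher, 4014 lower) with median centring, which shifted the median of all genes by -0.116. The share was 55.9% with the mean of all probe sets of a gene and 54.5% with probe sets tested singly. In PC9 these 2 settings gave 56.6% and 56.5%. Tested against a 1.5-fold change, 1076 genes passed. The ratio of 3' to 5' signal of the actin control probe sets, a sign of RNA or amplification quality, was 3.03 ± 0.596 on the HCC827 erlotinib arrays and 2.17 ± 0.0586 on the HCC827 DMSO arrays, and the GAPDH ratio was 1.37 ± 0.151 against 1.17 ± 0.02 (exact permutation p = 0.1, two-sided, for each, the smallest that 3 against 3 allow). In PC9 the actin ratio was 2.22 ± 0.272 with erlotinib and 2.18 ± 0.15 with DMSO (exact permutation p = 1, two-sided). The GAPDH ratio there was 1.18 ± 0.0153 with erlotinib and 1.15 ± 0.0208 with DMSO (exact permutation p = 0.2, two-sided). Whether 3' bias in HCC827 lowered its share of higher genes with other probe sets was not tested. The same holds for single genes given with the mean of their probe sets. With the log2 actin ratio as a covariate 4152 genes changed in HCC827, and without erlotinib replicates 2 and 3, which had the highest actin ratios, 4402 changed; both alternatives were chosen after seeing the data.

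ERK pathway output genes fell in HCC827 in 13 of 20 cases, rose in 3 and did not pass in 4 (median -0.67, adjusted p = 1.50e-04; adjusted p = 0.103 with an estimated correlation). DUSP6 fell by 1.76 ± 0.12, SPRY4 fell by 1.51 ± 0.10, ETV4 fell by 0.91 ± 0.15, ETV5 fell by 0.69 ± 0.10 and CCND1 fell by 0.66 ± 0.06. Mitosis genes fell in 21 of 24 cases and did not pass in 3 (median -0.43, adjusted p = 1.79e-10; adjusted p = 0.103 with an estimated correlation). Among them PLK1 fell by 1.03 ± 0.09, MKI67 fell by 0.83 ± 0.09 and NUF2 of the kinetochore fell by 0.69 ± 0.07. DNA replication genes fell in 23 of 25 cases and did not pass in 2 (median -0.44, adjusted p = 1.07e-10; adjusted p = 0.103 with an estimated correlation). The licensing factor CDT1 fell by 1.18 on the log2 scale, and POLE2 went from a signal of 621 ± 11.9 to 322 ± 28.2. Ribosome biogenesis genes fell in 6 of 15 cases, rose in 1 and did not pass in 8 (median -0.14, adjusted p = 0.00716; adjusted p = 0.21 with an estimated correlation), and 12 fell with median centring (median -0.25). Among them NIP7 fell by 0.61 ± 0.06. Glycolysis genes fell in 8 of 19 cases, rose in 1 and did not pass in 10 (median -0.097, adjusted p = 0.0158; adjusted p = 0.344 with an estimated correlation), and 10 fell with either other scaling (median -0.17 and -0.21). PDK1 went from a signal of 966 ± 32.1 to 746 ± 88.2. Without HCC827 erlotinib replicate 1 the medians were -0.065 for ribosome biogenesis, -0.034 for glycolysis (adjusted p = 0.0696) and -0.035 for cholesterol synthesis, and the last was -0.052 without HCC827 DMSO replicate 3. Cholesterol synthesis genes fell in 7 of 18 cases, rose in 3 and did not pass in 8 (median -0.094, adjusted p = 0.0277; adjusted p = 0.21 with an estimated correlation, 0.0623 with the stricter filter). With median centring 8 cholesterol synthesis genes fell (median -0.21). INSIG1, a sterol sensor, fell by 0.83 ± 0.07 and the sterol carrier STARD4 fell by 0.85 ± 0.14. With the actin ratio as a covariate 18 mitosis, 20 DNA replication and 5 glycolysis genes fell in HCC827.

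Interferon response genes fell in HCC827 in 14 of 23 cases, rose in 2 and did not pass in 7 (median -0.54, adjusted p = 3.37e-05; adjusted p = 0.111 with an estimated correlation). IFI44L went from a signal of 1012 ± 35.0 to 357 ± 63.2 and IFI44 from 1703 ± 85.6 to 700 ± 37.8. The 2 that rose did not rise with median centring. Beside the raised actin ratio of 3.03 on these erlotinib arrays, 10 members fell and 0 rose with the ratio as a covariate. Antigen presentation genes did not pass as a list (8 of 16 rose, 2 fell, median 0.24, adjusted p = 0.14; 0.0475 with no filter, 0.0379 with the stricter filter and 0.0122 with the mean of all probe sets), with HLA-DMA up by 1.02 ± 0.11 and HLA-E by 0.61 ± 0.06.

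NF-kB target genes rose in HCC827 in 13 of 18 cases and 5 did not pass (median 0.55, adjusted p = 0.00259; adjusted p = 0.21 with an estimated correlation), and 1 fell under quantile normalization and under median centring. IL6 rose by 2.32 ± 0.12 and CXCL1 by 1.19 ± 0.17 beside CCL2. Mesenchymal genes rose in 14 of 20 cases, fell in 3 and did not pass in 3 (median 0.90, adjusted p = 0.00917; adjusted p = 0.118 with an estimated correlation). The median was 0.49 with 32 in place of 8 and 0.59 (adjusted p = 0.0324) with the mean of all probe sets, and the fibroblast marker LUM rose by 3.77 on the same arrays. SPARC rose from a signal of 34.5 ± 1.78 to 358 ± 14.9, TAGLN rose by 2.58 ± 0.12, COL5A1 by 1.45 ± 0.11 and VIM by 0.98 ± 0.27. Lysosome and autophagy genes rose in 13 of 16 cases, 1 fell and 2 did not pass (median 0.44, adjusted p = 6.10e-04; adjusted p = 0.118 with an estimated correlation). GABARAPL1 rose by 2.31 ± 0.14 and WIPI1 by 1.89 ± 0.11. Stress response genes rose in 12 of 16 cases and 4 did not pass (median 0.42, adjusted p = 4.56e-04; adjusted p = 0.103 with an estimated correlation). ATF3 rose by 2.77 ± 0.15. CDK inhibitors and FOXO target genes rose in 12 of 17 cases, 2 fell and 3 did not pass (median 0.37, adjusted p = 0.00449; adjusted p = 0.198 with an estimated correlation). PIK3IP1 rose by 2.78 ± 0.17, SESN3 by 2.19 ± 0.27 and CDKN1C by 1.96 ± 0.18. CDKN1B rose by 0.33 ± 0.07, and by 0.16 (adjusted p = 0.226) with the actin ratio as a covariate. YAP and TAZ target genes rose in 14 of 20 cases, 2 fell and 4 did not pass (median 0.43, adjusted p = 0.00716; adjusted p = 0.21 with an estimated correlation). ANKRD1 rose by 3.36 ± 0.25 and CCDC80 by 1.71 ± 0.07. With the covariate the median of the YAP and TAZ target genes was 0.27 (adjusted p = 0.0299). With it 13 mesenchymal, 10 NF-kB, 10 lysosome, 10 stress response, 9 YAP and TAZ and 8 CDK inhibitor and FOXO target genes rose.

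Receptor tyrosine kinases and adaptors rose in HCC827 in 10 of 16 cases, fell in 2 and did not pass in 4 (median 0.36, adjusted p = 0.0372; adjusted p = 0.118 with an estimated correlation, 0.0642 with quantile normalization, 0.0692 with the stricter filter, 0.479 with the mean of all probe sets and 0.0619 with the 6 HCC827 arrays alone). INSR rose by 1.62 ± 0.06, FGFR3 by 1.17 ± 0.10, IGF1R by 1.01 ± 0.09 and AXL by 0.63 ± 0.07. With the actin ratio as a covariate 8 of these receptors and adaptors rose and 1 fell. ERBB3 rose by 0.40 ± 0.07, although 1 of its other probe sets was called lower and the mean of its probe sets was 0.13 (adjusted p = 0.133). EGFR had a change of -0.002 ± 0.055 (adjusted p = 0.976), and of -0.38 (adjusted p = 8.80e-04) with the mean of its probe sets. MET fell by 0.14 ± 0.04 (adjusted p = 0.017), which missed the threshold without HCC827 DMSO replicate 2 (-0.12, adjusted p = 0.0771) and without HCC827 erlotinib replicate 1 (-0.12, adjusted p = 0.0508) or 2 (-0.13, adjusted p = 0.0596). With the actin ratio as a covariate its adjusted p was 0.0932, and the mean of its probe sets fell by 1.03 (adjusted p = 1.19e-06). BCL2 family genes rose in 5 of 17 cases and fell in 4 (median 0.12, adjusted p = 0.94), and with median centring 3 rose and 5 fell (median 0.004). BMF rose by 1.90 ± 0.10. BCL2L11 rose by 0.44 ± 0.09, although 1 of its other probe sets was called lower and the mean of its probe sets was 0.033 (adjusted p = 0.677). Epithelial genes rose in 8 of 20 cases and fell in 5 (adjusted p = 0.94), with a median of 0.065, a mean of 0.10 and a test pointing down, and with median centring 4 rose and 7 fell (median -0.051). CLDN1 rose by 2.67 ± 0.08, and MUC1 fell by 1.54 ± 0.12. CDH1 had a change of 0.015 ± 0.061 (adjusted p = 0.852), which was -0.51 with the mean of its probe sets, -0.026 with quantile normalization and -0.10 with median centring.

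EGFR family ligands in HCC827 rose in 2 of 7 cases and fell in 3 (adjusted p = 0.379), with a median of -0.26, a mean of 0.093 and a test pointing down. HBEGF rose by 2.23 ± 0.09 and TGFA fell by 0.52 ± 0.08. Lung epithelial lineage genes rose in 3 of 12 cases and fell in 1 (adjusted p = 0.993), with a median of -0.028, a mean of 0.12 and a test pointing up. The alveolar HOPX rose by 1.51 ± 0.12 and the protease NAPSA fell by 1.94 ± 0.13. Stem-like and drug-tolerance marker genes rose in 6 of 13 cases and fell in 1 (median 0.23, adjusted p = 0.271, or 0.033 with no filter), with KDM5B up by 0.93 ± 0.07. With median centring 4 of these markers rose and 3 fell (median 0.11). Of the 4 leukocyte, endothelial and fibroblast markers tested, LUM rose by 3.77 ± 0.14 to a signal of 183 ± 17.5 and 3 did not pass (adjusted p = 0.292). Adjusted over the list alone, ERK output genes split into 4 higher and 14 lower and DNA replication genes into 1 higher and 24 lower, and 6 BCL2 family, 9 epithelial and 3 interferon genes rose, the counts of the other 16 lists being as given.

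The overlap between the lines asked which changes they had in common. FILIP1L rose by 4.51 ± 0.08 in PC9 and 4.16 ± 0.08 in HCC827, MAP2 by 3.78 ± 0.11 and 3.98 ± 0.11, IL32 by 5.93 ± 0.12 and 3.66 ± 0.12 and the proteoglycan LUM by 3.57 ± 0.14 and 3.77 ± 0.14. The pregnancy-specific glycoprotein PSG5, NATD1, the tubulin TUBA1A and ANKRD1 also rose by 2.99 or more in both. Among shared decreases the collagenase MMP1 had log2 changes of -3.19 ± 0.14 in PC9 and -2.54 ± 0.14 in HCC827, the calpain CAPN8 -2.60 ± 0.12 and -2.42 ± 0.12, and the transporter ABCC2 -2.41 ± 0.13 and -2.11 ± 0.13. TCN1, SERPINB3, ACOX2, CALB1 and MALL fell in both as well. These 16 genes were chosen after their values were seen, as those with the largest smaller change of the pair.

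In all, 4203 genes changed in the same direction in both lines: 2674 higher, against 1545 for independent lists (odds ratio 5.46), and 1529 lower, against 729 (odds ratio 5.59). Opposite directions were called for 710 genes, fewer than for independent lists: 303 higher in PC9 and lower in HCC827, against 935 (odds ratio 0.182), and 407 the reverse, against 1204 (odds ratio 0.178). Of the genes changed at least 2-fold in both lines, 357 rose, 53 fell and 19 went opposite ways. Across genes, which are not independent replicates, the log2 changes had Pearson r = 0.489 and Spearman rho = 0.515, and 2810 of the 4203 shared genes had the larger change in PC9. With the actin ratio as a covariate 2793 genes changed in the same direction in both lines.

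**Figure D2:**
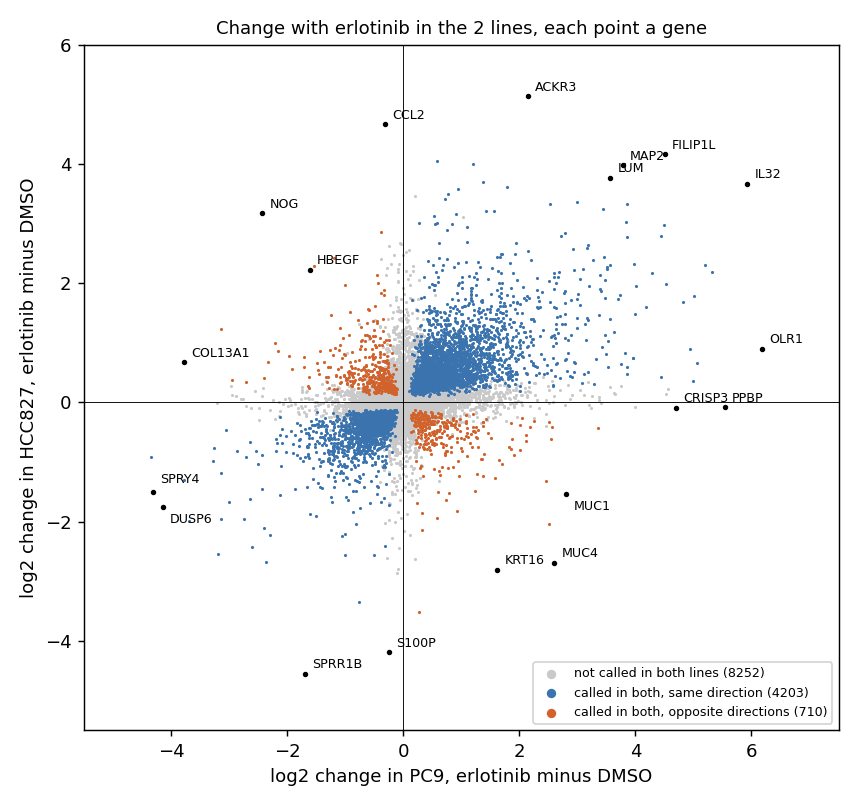
Log2 change with erlotinib in PC9 (x axis) against HCC827 (y axis) for 13165 genes, coloured by whether the gene changed in the same direction in both lines (4203), in opposite directions (710) or otherwise (8252). Labelled genes include the largest changes of each line, such as OLR1 (6.18 in PC9) and ACKR3 (5.13 in HCC827).

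**Figure D3:**
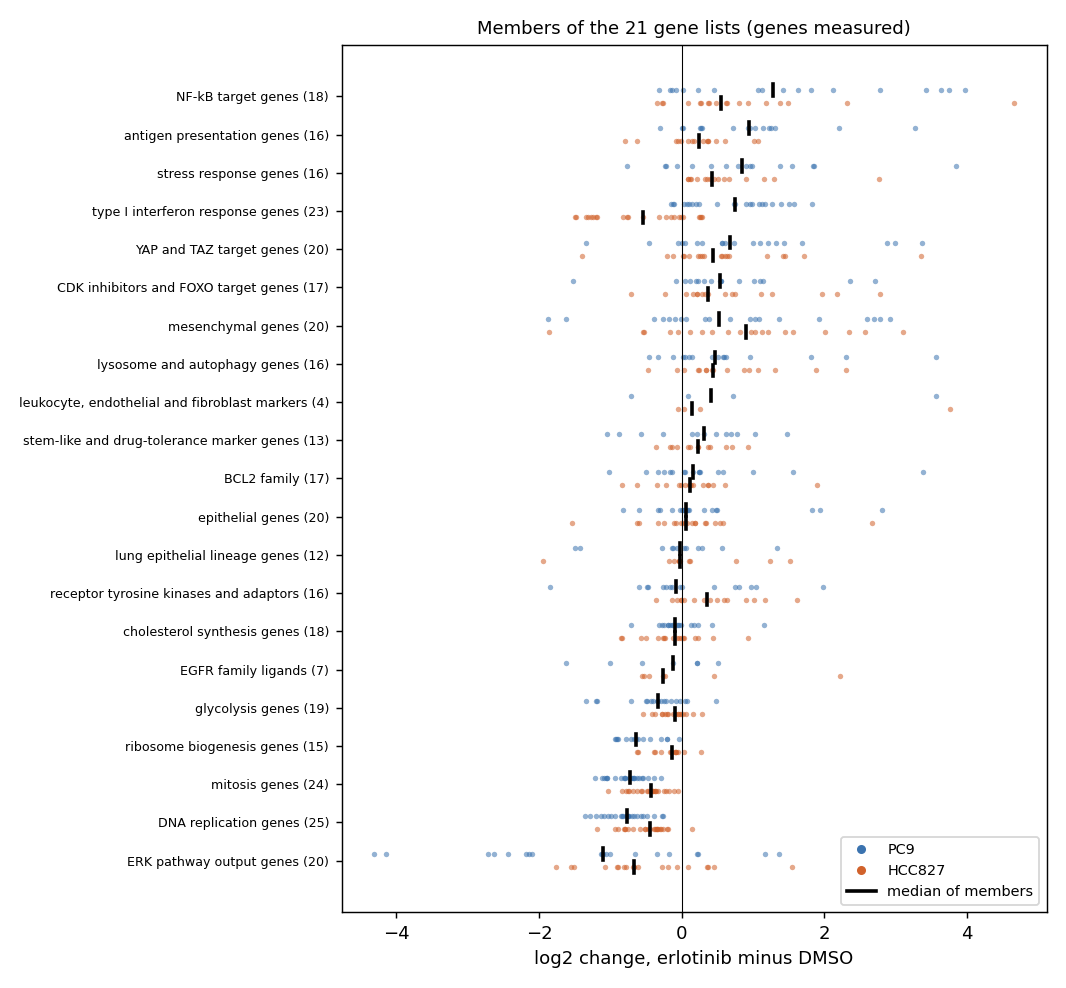
Log2 change with erlotinib of each measured member of the 21 gene lists (points) with the list median (black bar), PC9 above HCC827 within each list; the number of members is in brackets. NF-kB target genes had the highest median in PC9 (1.28) and mesenchymal genes in HCC827 (0.90), while ERK output genes had the lowest in both (-1.10 and -0.67); with median centring the medians of epithelial genes in both lines and of BCL2 family genes in PC9 were below 0.

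The change with erlotinib itself differed between the lines for 5954 of 13165 genes (45.2%), more positive in PC9 for 2799 and in HCC827 for 3155, and by at least 2-fold for 762 and 586. This balance was not stable: with the mean of all probe sets 2942 were more positive in PC9 and 2613 in HCC827, with probe sets tested singly 5674 and 4851, with the actin ratio as a covariate 2258 and 2215, and without HCC827 erlotinib replicates 2 and 3 2107 and 2093. PPBP rose in PC9 and had a change of -0.085 ± 0.133 in HCC827 (adjusted p = 0.619), a difference of 5.63 ± 0.19. The mucin MUC4 rose by 2.60 ± 0.13 in PC9 and fell by 2.69 ± 0.13 in HCC827, a difference of 5.29 ± 0.18. OLR1 differed by 5.28 ± 0.20 and the secreted protein CRISP3 by 4.79 ± 0.17, with a PC9 signal that went from 0.267 ± 0.208 to 208 ± 25.8. NOG, an antagonist of bone morphogenetic proteins, fell in PC9 from a signal of 1602 ± 207 to 289 ± 22.7 and rose in HCC827 from 62.8 ± 6.06 to 631 ± 43.3, a difference of -5.61 ± 0.14 (adjusted p = 2.11e-13). CCL2 differed by -4.99 ± 0.30, COL13A1 by -4.45 ± 0.20 and SH3RF3 by -4.37 ± 0.27. The size of a change from a signal near 0 depended on the constant added: with 1 or 32 in place of 8, the difference for CRISP3 was 7.85 or 2.91.

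Of the 21 lists, 10 differed between the lines. Interferon response genes had a median difference of 1.30, with 20 of 23 members more positive in PC9 and 3 not passing (adjusted p = 2.34e-11; adjusted p = 0.0301 with an estimated correlation); IFI44 differed by 2.85 ± 0.18 and MX2 by 1.55 ± 0.17. Antigen presentation genes differed by a median of 0.67, with 13 of 16 more positive in PC9 and 1 in HCC827 (adjusted p = 9.39e-05; adjusted p = 0.0298 with an estimated correlation), PSMB9 by 2.97 ± 0.12. NF-kB target genes differed by 0.90, with 11 of 18 more positive in PC9 and 3 in HCC827 (adjusted p = 0.00701; adjusted p = 0.454 with an estimated correlation), and the median was 0.42 with 32 in place of 8 and 0.59 with the mean of all probe sets. ICAM1 differed by 3.11 ± 0.12 and CXCL1 by 2.45 ± 0.24. YAP and TAZ target genes differed by 0.31, with 11 of 20 more positive in PC9 and 3 in HCC827 (adjusted p = 0.0214; adjusted p = 0.454 with an estimated correlation), CCN2 by 1.92 ± 0.34. The raised actin ratio of 3.03 belonged to 1 arm of each of these contrasts, and with it as a covariate 4473 genes differed.

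The other 6 lists were more negative in PC9. ERK output genes differed by a median of -0.71 (12 of 20 more negative in PC9, 2 more positive, adjusted p = 1.02e-04; adjusted p = 0.0958 with an estimated correlation), and the median was -0.40 with the mean of all probe sets. DUSP6 differed by -2.39 ± 0.17, ETV5 by -1.41 ± 0.14, and CCND1 by 0.32 ± 0.09. For CCND1 the adjusted p was 0.0949 with the actin ratio as a covariate and 0.0819 without HCC827 erlotinib replicates 2 and 3. Ribosome biogenesis genes differed by -0.35 (12 of 15, adjusted p = 2.94e-04; adjusted p = 0.221 with an estimated correlation), POLR1B by -0.79 ± 0.08. DNA replication genes differed by -0.34 (15 of 25, adjusted p = 0.00156; adjusted p = 0.316 with an estimated correlation), GINS2 by -0.68 ± 0.10. Mitosis genes differed by -0.25 (9 of 24, adjusted p = 0.00538; adjusted p = 0.454 with an estimated correlation), NUF2 by -0.38 ± 0.10, whereas the difference was -0.060 ± 0.133 for PLK1 (adjusted p = 0.738) and -0.016 ± 0.128 for MKI67 (adjusted p = 0.931). Receptor tyrosine kinases and adaptors differed by -0.39 (9 of 16 against 2, adjusted p = 0.0287; adjusted p = 0.145 with an estimated correlation, 0.0832 with the stricter filter and 0.291 with the mean of all probe sets). IRS1 differed by -1.49 ± 0.12, AXL by -0.63 ± 0.10 and ERBB3 by 0.42 ± 0.09. EGFR differed by -0.48 ± 0.08 and by -0.19 (adjusted p = 0.181) with the mean of its probe sets, and MET differed by -0.34 ± 0.06 and by 0.58 with the mean of its probe sets. Glycolysis genes differed by -0.24 (10 of 19 against 2, adjusted p = 0.0292; adjusted p = 0.555 with an estimated correlation), which missed the threshold without PC9 DMSO replicate 1 (-0.23, adjusted p = 0.0598), without HCC827 erlotinib replicate 2 (-0.21, adjusted p = 0.0536) and without HCC827 erlotinib replicates 2 and 3 (-0.14, adjusted p = 0.164). It also missed it with quantile normalization (-0.145, adjusted p = 0.124), the mean of all probe sets (-0.19, adjusted p = 0.232), variances without the trend (adjusted p = 0.0622) and the actin ratio as a covariate (-0.22, adjusted p = 0.0631). PDK1 differed by -0.96 ± 0.14.

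No difference between the lines passed for 11 lists. In the BCL2 family the median difference was 0.21 (6 of 17 more positive in PC9, 2 in HCC827, adjusted p = 0.161), with BMF differing by 1.49 ± 0.14 and BCL2L11 by 0.56 ± 0.12. Epithelial genes had 0.034 (5 of 20 against 3, adjusted p = 0.75; -0.014 with median centring), with MUC1 differing by 4.35 ± 0.17. EGFR family ligands had -0.003 (3 of 7 against 2, adjusted p = 0.895; 0.007 with quantile normalization), with HBEGF differing by -3.84 ± 0.13. Median, mean and test differed in sign for CDK inhibitors and FOXO target genes (-0.069, -0.093, up, adjusted p = 0.979, 4 of 17 each way), mesenchymal genes (-0.060, -0.11, up, adjusted p = 0.895, 6 of 20 against 7) and lysosome genes (-0.063, 0.015, down, adjusted p = 0.884, 2 of 16 against 6). Lung lineage genes had -0.087 (2 of 12 against 5, adjusted p = 0.56), cholesterol synthesis genes 0.077 (6 of 18 against 1, adjusted p = 0.293), stress response genes 0.10 (6 of 16 against 4, adjusted p = 0.369) and stem-like markers 0.10 (2 of 13 against 3, adjusted p = 0.895). Leukocyte, endothelial and fibroblast markers had -0.028 (1 of 4 each way, adjusted p = 0.895). Adjusted over the list alone, the difference was called in 16 DNA replication, 21 interferon, 4 and 0 cholesterol synthesis genes, 5 and 5 epithelial genes, 11 and 4 NF-kB targets and 2 and 11 glycolysis genes, more positive and more negative in PC9 where both are given.

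**Figure D4:**
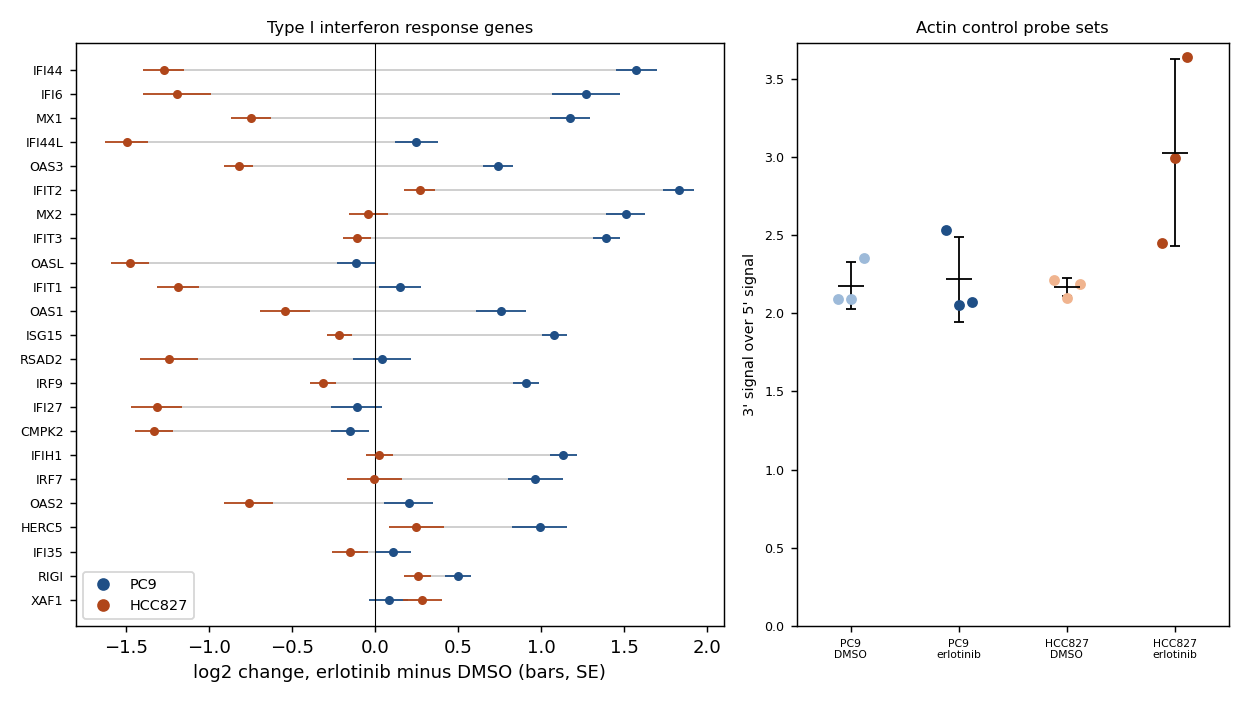
Left, log2 change with erlotinib (± SE) of the 23 measured interferon response genes in PC9 and HCC827; right, ratio of 3' to 5' signal of the actin control probe sets on each array (points) with mean and SD of 3 arrays. In PC9 14 genes rose and none fell (1 fell with quantile normalization, 2 with median centring), in HCC827 14 fell and 2 rose (0 with median centring), and the HCC827 erlotinib arrays had ratios from 2.45 to 3.64.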

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

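The tests of 3' bias for the interferon genes of either line were chosen, or had their bound set, only after results had been seen. The fits with the actin ratio as a covariate and without HCC827 erlotinib replicates 2 and 3 were also added then.

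The genes and lists given below with a difference were singled out because the change with erlotinib differed between the lines. In all 5954 genes differed. With line labels redrawn within each treatment, after the mean of each line was removed, 1 of 100 splits (the real one) gave as many genes, and the highest other gave 0. For lists, 1 of 100 splits gave as many as the 10 seen, and the highest other gave 9, so the number of lists stood only just above a redrawn grouping. A redrawn grouping can mix the lines unevenly and so keep part of their difference. Genes changed in the same direction in both lines numbered 4203, and 1 of 100 splits with treatment labels redrawn (the real one) gave as many. The highest other gave 710, which is the split that swaps all labels of 1 line and so repeats the genes of opposite direction, and the highest without it gave 0. Most other splits put both treatments, or both lines, into 1 group, which widened the spread within groups. Their counts of 0 genes were thus largely set in advance. They cannot decide whether the 5954 or the 4203 genes came from the line or the treatment.

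For each line alone the 10 splits of 6 arrays are too few for a share under 0.05. In PC9 8521 genes changed, with 0 in the highest other split (1 of 10 as large, the real one), and in HCC827 6818, with 0 (1 of 10). For gene lists in PC9, 2 of 10 splits gave as many as the 12 seen, the highest other also giving 12, and in HCC827 1 of 10 gave as many as the 14 seen, the highest other giving 11. List calls at the preset correlation thus arose in other splits of the same arrays. Every other split mixed the treatments unevenly, so it kept part of their difference and widened the spread within groups. The splits therefore cannot decide whether the list or gene calls came from the treatment. With an estimated correlation 3 lists passed in PC9 and 0 in HCC827.

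Type I interferon response genes rose in PC9 and fell in HCC827, a median difference of 1.298. With an estimated correlation adjusted p = 0.2 in PC9, 0.111 in HCC827 and 0.0301 for the difference, and 9 and 7 of 23 members did not pass. The tables argue against scaling of the arrays as the cause, since the smaller difference under the other scalings was 1.225. In PC9 the actin 3'/5' ratios of the arms were close (2.18 ± 0.15 and 2.22 ± 0.272), so that a fit with the ratio as a covariate (median 0.762) could decide nothing. For HCC827, 3' bias cannot be told apart from the treatment for part of the fall: the median of -0.544 became -0.42 with the covariate (adjusted p = 1.90e-04) and -0.367 without replicates 2 and 3 (adjusted p = 1.16e-04), so it kept its direction and lost size. Noise of dim probe sets stayed undecided in PC9, where only 3 of 23 members were bright (median 1.08), and the biology of the lines, the plated cell number and any handling batch that went with the line remain untested. The pattern describes the list only. Outside the list, the interferon-inducible GBP1 rose by 5.06 in PC9 and 0.65 in HCC827, and CXCL10 by 0.77 and 3.49.

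Genes called in opposite directions in the lines numbered 710. The lower count under the other scalings was 712. Whether these were the same genes was not tested, so the count leaves scaling of the arrays open. Of 385 such genes with another probe set, 71.7% had the same 2 signs on the next brightest one, which leaves the choice of probe set open for the rest. With the actin ratio as a covariate 99.6% kept both signs. Of the 2811 HCC827 calls lost with that covariate, 99.3% kept their sign too. Kept signs therefore cannot decide whether 3' bias played a part. A handling batch that went with the line cannot be told apart from the lines. The dap spike-in signal also separated the lines (605 in PC9 DMSO, 69.8 in HCC827 DMSO). It did not separate the arms of a line (604 in PC9 erlotinib, 72.8 in HCC827 erlotinib).

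The other lists that differed between the lines are given as medians. ERK pathway output genes had -0.71, receptor tyrosine kinases and adaptors -0.391, mitosis genes -0.251, DNA replication genes -0.335, glycolysis genes -0.244 and ribosome biogenesis genes -0.349. With an estimated correlation none of these 6 passed (adjusted p = 0.0958, 0.145, 0.454, 0.316, 0.555 and 0.221). Antigen presentation genes had 0.674, NF-kB target genes 0.898 and YAP and TAZ target genes 0.308, and with an estimated correlation adjusted p = 0.0298, 0.454 and 0.454.

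Single genes that differed between the lines were PPBP (5.627), MUC4 (5.29), OLR1 (5.282) and CRISP3 (4.789), and in the other direction NOG (-5.607), CCL2 (-4.991), COL13A1 (-4.45) and SH3RF3 (-4.369). Among the genes named whatever their result, the differences were EGFR -0.478, ERBB3 0.415, MET -0.337, AXL -0.63, BCL2L11 0.563, DUSP6 -2.391, CCND1 0.324 and ETV5 -1.412. CCND1 was not called with the actin ratio as a covariate (0.248). With the mean of all probe sets MET turned to 0.578 and EGFR was not called (-0.187, adjusted p = 0.181).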

How the results depend on the processing

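The fits with the actin 3'/5' ratio as a covariate and without HCC827 erlotinib replicates 2 and 3 were chosen only after results had been seen. Without detection calls, signal over background was the only measure of presence, which limits folds that start near 0: the log2 change of CRISP3 in PC9 was 7.371 with 1 added and 2.889 with 32. Among the 118 named genes, many picked for large changes, called results kept direction and call in 5380 combinations of result and setting. They lost the call in 169 and turned in 1. For the called lists the numbers were 844, 46 and 0. The other called genes were not counted this way. Some settings, such as variances without the trend or an array of the other line left out, cannot move the log2 change in a line. There the kept direction was fixed in advance, so the kept counts overstate how stable the results were.

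Tested singly, probe sets gave 15694 changed in PC9, 12521 in HCC827, 10525 differing between the lines and 7435 changed alike in both; more probe sets than genes were tested. Against a 1.5-fold change 2202 genes passed in PC9 and 1076 in HCC827, a stricter question by construction. Without HCC827 erlotinib replicates 2 and 3, 4402 genes changed in HCC827; with the actin ratio as a covariate 4152 changed there and 2793 changed alike in both lines. Counts of at least 2-fold in HCC827 were 750 higher and 202 lower without those replicates and 722 and 204 with the covariate, against 760 and 193. Of the calls lost, 2538 without those replicates had a median size of 0.326 before and 0.257 after, with a median standard error of 0.0975 and 0.137. With the covariate the 2811 lost calls had 0.34 and 0.258, with 0.098 and 0.145, so errors grew and sizes shrank. Genes picked because their call was lost favour smaller sizes after the refit, so the shrinkage decides nothing. Whether 3' bias is part of these small changes stays open. With an estimated correlation 3 lists passed in PC9, 0 in HCC827 and 2 for the difference between the lines.

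Medians of called lists also moved by more than 1.5 times. With pseudocount 32 these were type I interferon response genes in PC9 0.473 and receptor tyrosine kinases and adaptors in HCC827 0.207. With the mean of all probe sets cholesterol synthesis genes and glycolysis genes in HCC827 both had -0.156, and ribosome biogenesis genes in HCC827 -0.249. Glycolysis genes in HCC827 had -0.152 with the actin ratio as a covariate. Without HCC827 erlotinib replicates 2 and 3 cholesterol synthesis genes in HCC827 had -0.171, glycolysis genes in HCC827 -0.211 and YAP and TAZ target genes for the difference 0.462. Receptor tyrosine kinases and adaptors in HCC827 had 0.219 with quantile normalization, 0.181 with no filter, 0.181 with the 70th percentile filter and 0.177 with the mean of all probe sets, which gave -0.137 for their difference. Cholesterol synthesis genes in HCC827 had -0.050 with the 70th percentile filter. The cause was not tested.

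With each array left out in turn, genes changed ranged from 7913 to 8525 in PC9, from 5958 to 7101 in HCC827, from 5268 to 5946 for the difference and from 3737 to 4292 for both lines alike. Lists changed ranged from 12 to 13 in PC9, from 13 to 14 in HCC827 and from 9 to 10 for the difference.

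Replicate number as a block, a pairing that the labels do not state, gave 8438 genes in PC9, 6661 in HCC827, 5760 for the difference and 4103 alike in both. Deviations of arrays with the same number had correlations of -0.26, -0.194 and -0.024 in PC9 and 0.011, 0.132 and 0.013 in HCC827. Arrays with unlike numbers had values from -0.142 to 0.237. These few values gave no clear sign of a pairing and cannot exclude one.

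Values that turned sign belonged, except for MET, to results that were not called; the cause was not tested. With median centring these were BCL2 family in PC9 -0.005, epithelial genes in PC9 -0.106, in HCC827 -0.051 and for the difference -0.014, AXL in PC9 -0.159, and CDH1 in PC9 -0.079 and in HCC827 -0.101. With quantile normalization they were EGFR family ligands for the difference 0.007 and CDH1 in HCC827 -0.026. With the mean of all probe sets they were MET for the difference 0.578, CDH1 in HCC827 -0.508, AXL in PC9 -0.032, epithelial genes in HCC827 -0.009, and for the difference EGFR family ligands 0.288, CDK inhibitors and FOXO target genes 0.206, mesenchymal genes 0.020 and lysosome and autophagy genes 0.009. With no filter lung epithelial lineage genes in PC9 had 0.017 and leukocyte, endothelial and fibroblast markers in PC9 -0.069, and with the 70th percentile filter the former had 0.028. With pseudocount 1 lung epithelial lineage genes in HCC827 had 0.048 and the leukocyte, endothelial and fibroblast markers for the difference 0.099. With pseudocount 32 EGFR family ligands for the difference had 0.226 and mesenchymal genes 0.038. With the actin ratio as a covariate the differences were CDK inhibitors and FOXO target genes 0.056, lung epithelial lineage genes 0.023 and leukocyte, endothelial and fibroblast markers 0.077. Without HCC827 erlotinib replicates 2 and 3 lung epithelial lineage genes in HCC827 had 0.041, CDH1 in HCC827 -0.070 and EGFR family ligands for the difference 0.107.

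With 1 array left out, uncalled values that turned sign ranged as follows. Lung epithelial lineage genes went from -0.131 to 0.086 in PC9 and from -0.102 to 0.092 in HCC827, EGFR family ligands for the difference from -0.201 to 0.141 and epithelial genes for the difference from -0.048 to 0.103. For the difference, mesenchymal genes went from -0.146 to 0.041, lung epithelial lineage genes from -0.242 to 0.035 and leukocyte, endothelial and fibroblast markers from -0.129 to 0.067. AXL in PC9 went from -0.008 to 0.025, CDH1 in HCC827 from -0.026 to 0.058 and EGFR in HCC827 from -0.038 to 0.046.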

Other observations

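The groupings in this part were chosen only after values had been seen: 12 gene families defined by their symbols were counted. Pregnancy-specific glycoprotein genes (PSG) rose in 7 of 7 cases in both lines, such as PSG1 by 3.47 in PC9 and 1.76 in HCC827. Whether probes of this family tell its members apart was not tested, so the 7 cases may not be separate ones. Collagen genes (COL) rose in 16 of 23 cases in PC9 and fell in 3, and rose in 13 and fell in 2 in HCC827 (4 fell under the other scalings), with the basement membrane collagen COL4A4 up by 4.28 and 2.18. CXCL chemokines rose in 9 of 10 cases in PC9 and in 8 in HCC827, where 1 fell; CXCL8 rose by 3.43 and 0.93 and the interferon-inducible CXCL10 by 0.77 and 3.49.

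S100 calcium-binding genes fell in 12 of 14 cases in PC9 and 10 in HCC827, with S100A8 at -3.06 and -0.46 and S100A4 at -1.87 and -0.54; none rose, except 1 in PC9 under quantile normalization. The xenobiotic-metabolising CYP1 genes rose in 3 of 3 cases in both lines, CYP1A1 by 1.37 in PC9 and 3.70 in HCC827. Of the other families, keratins (KRT) rose in 6 and fell in 4 of 17 cases in PC9 and 4 and 5 in HCC827, and tubulins (TUB) rose in 6 and fell in 5 of 13 cases and 4 and 5. Interleukins (IL) rose in 5 and fell in 1 of 11 cases in PC9 and 7 and 2 in HCC827, and mucins (MUC) rose in 4 of 8 cases in PC9 but rose in 2 and fell in 4 in HCC827. HLA genes rose in 8 of 11 cases in PC9 and rose in 5 and fell in 1 in HCC827. Whether the probe sets tell HLA or CYP1 genes apart was not tested either, so their cases may not be separate ones. SPRR genes rose in 1 and fell in 2 of 3 cases in PC9 and fell in 3 in HCC827, and SERPINB genes rose in 1 and fell in 3 of 5 cases in PC9 and fell in 4 in HCC827. Under the other scalings more fell than rose among tubulins in PC9 (5 and 6, median centring), and 0 SERPINB genes rose in PC9 (median centring). In HCC827 tubulins rose in 3 and fell in 7 cases with quantile normalization and 4 and 8 with median centring. Keratins there rose in 5 and fell in 6 and rose in 4 and fell in 7.

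PC9 DMSO replicate 2 stood apart from the other arrays of its group. On it 23 genes were at least 2-fold above both other arrays and 0 were below, against 0 to 2 above on any other array. PC9 DMSO replicate 1 had 12 genes at least 2-fold below both others, the most below on any array. CLDN11 read 91.3 against 10.4 and 9.90, MYLK 126 against 24.7 and 22.6, and the neural cadherin CDH2 34.5 against 2.10 and 3.20. What set the array apart was not tested.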
